A study of Homo sapiens with 8 samples.

How the data were processed

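Total RNA of 8 libraries was measured by strand-specific paired-end sequencing, per the submitters' labels. Each of the 4 groups, DND-41 or MOLT-4 cells treated with ACBI-1 or with the solvent DMSO for 24 h, held 2 libraries. Per the submitters' processing notes, reads were aligned to hg19 with STAR 2.5.2a, counted per gene with featureCounts and compared with DESeq2 1.12.4. The featureCounts version, the strand setting, the annotation release and the handling of reads that map to several places were not given in the sources used here. Reads of genes that overlap on opposite strands, or of close paralogs, can therefore have moved between genes in ways that the counts do not show. Shares of a gene's counts held by a gene on the opposite strand are given over all 8 libraries of both lines, not per line. An annotation of hg19 was not used here, so no coordinates are given.

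The authors deposited raw counts per Ensembl gene, 1 table per cell line with 63677 genes each, and the values were checked to be whole numbers with a different total in each library. The authors also deposited 1 DESeq2 table per cell line with log2 fold changes and their standard errors (unit log2). The same deposited tables hold a p-value and an adjusted p-value per gene. Their last kind of value is a Wald score, the deposited log2 fold change divided by its standard error. Per the file headers, the MOLT-4 count columns carry the suffix "redo", which the sources used here do not explain. Each count column was assigned to its group by the treatment and number in its name, and 0 columns were left unassigned. Gene types and exon lengths came from GENCODE release 29, which held 52526 of the gene identifiers.

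Each cell line was tested on its own with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, 2-sided, TMM scaling, low-count genes removed with filterByExpr). The difference between the lines was tested as the interaction of line and treatment in 1 edgeR fit of the 8 libraries. All p-values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. CPM are counts scaled to the TMM-adjusted library total, in the usual unit of that name. The 29 gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where a choice is said to have been made later. Lists with at least 5 members past the filter (25 in each line) were tested with camera from limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Camera sets the genes of a list against the other genes, while fry tests the list by itself. With an estimated correlation camera has only the residual degrees of freedom of the libraries, few with 2 libraries per group. Lists therefore pass less readily in that form. Lists share up to 4 members with other lists.

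The deposited fold changes were compared with DESeq2 1.42.0 fits of all 3 ways of splitting the 4 libraries of a line in pairs. The use of the deposited tables for DND-41, with cameraPR on the deposited Wald scores and a z test of the difference between both tables, was chosen after the data were examined. That z test divides the difference of the deposited log2 fold changes by the square root of the sum of their squared standard errors, and its p-values were adjusted by Benjamini and Hochberg. Since the direction of the deposited DND-41 table could not be checked, the comparisons of both tables were repeated with its signs turned. For the DND-41 lists, a smooth trend in exon length was also taken out of each library through offsets. Both repeats were chosen after the data were examined.

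Named genes followed a fixed rule. SMARCA2, SMARCA4, PBRM1 and VHL were always named. Per line, the 12 largest positive and 12 largest negative log2 fold changes were taken among protein-coding genes past the threshold that had a symbol other than a clone name, at least 5 CPM in the higher group and both ACBI-1 libraries on the same side of both DMSO libraries. For the interaction, 6 genes per direction were taken by the same conditions, with the separation of the libraries required in at least 1 line. For both lines together, the rule takes 6 genes per direction with the largest smaller change. Per list, up to 4 members with the smallest adjusted p were taken, or the 2 most abundant where none passed. The same rule, with a mean of at least 5 CPM over the 4 libraries of the line, was applied to the deposited tables.

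The steps were tested on simulated data, negative-binomial counts drawn with the fitted spread of each comparison and 200 changed genes. At true changes of 1.5-fold, 2-fold and 4-fold, the MOLT-4 test recovered 95.5%, 100% and 100% of the changed genes with 1 false call among 14287 genes. The DND-41 test recovered 1.49%, 2.99% and 74.2% with 6 false calls among 14217 genes. The simulated libraries were independent, while the real DND-41 libraries of the same number deviated together (correlation 0.849). The simulated shares therefore do not describe the DND-41 test, or the interaction test that uses those libraries, on the real data. For the interaction the shares were 0%, 1.49% and 60.6% with 0 false calls among 15694 genes, and for the z test they were 64.2%, 95.5% and 100% with 1 false call among 13040 genes. Both camera and cameraPR called a list shifted by 1.5-fold, and 0 of 23 other lists in DND-41 and 0 of 24 in MOLT-4. Genes were drawn independently as well, so this check cannot show false list calls where the genes of a list move together. In the real DND-41 libraries the estimated correlation was 0.654 for oxidative phosphorylation genes and 0.311 for cytosolic ribosomal protein genes.

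The alternatives were DESeq2 size factors (RLE), total counts without TMM, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2, limma-voom, a test against a 1.5-fold change, 1 fit of the 8 libraries, the replicate number as a block, and leaving out each library in turn. The numbers of the replicates were not taken as pairs in the main tests, because no label pairs them. Where 1 library is left out, the lone library of that group is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9. The 95% intervals of the odds ratios came from Fisher's exact test, and counting error of the genes is part of the fitted spread.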

Results

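RNA sequencing measured the transcripts of DND-41 and MOLT-4, established lines of human T-cell acute lymphoblastic leukaemia, after 24 h with 100 nM ACBI-1 or with the solvent DMSO. ACBI-1 is a PROTAC, a molecule that binds the bromodomains of the chromatin remodelling proteins SMARCA2, SMARCA4 and PBRM1 and brings them to the ubiquitin ligase VHL, which leads to their degradation. Each of the 4 groups of line and treatment held 2 libraries. Total counts in DND-41 were 21312665 and 21434952 in the libraries labelled ACBI-1 and 21308737 and 21815882 in those labelled DMSO. In MOLT-4 they were 21642039 and 21585964 with ACBI-1 and 22067644 and 21875856 with DMSO. Between 21636 and 23243 genes had a count in a library. Genes of the mitochondrial genome took 5.887% to 6.844% of counts in DND-41 and 8.859% to 9.673% in MOLT-4. The p-values measure only the spread between these libraries, which may be technical replicates, since the labels do not say how they were made.

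The libraries of MOLT-4 differed by treatment. Pairs of MOLT-4 libraries from the same group differed by 2.65 (ACBI-1) and 1.52 (DMSO) times the counting noise, as the chi-square per degree of freedom, and pairs from different groups by 49.4 to 50.8. The libraries of DND-41 differed by replicate number and not by the treatment in their names. There the libraries labelled ACBI-1 replicate 1 and DMSO replicate 1 differed by 5.49, and those labelled ACBI-1 replicate 2 and DMSO replicate 2 by 5.09. The pair labelled ACBI-1 differed by 68.3, the pair labelled DMSO by 64.6, and the other pairs by 63.2 and 75.5. In the authors' deposited table for DND-41, the log2 fold changes of all 27069 genes compared equalled, within 0.001, those of the libraries numbered 2 over those numbered 1. They equalled the fold changes of the labelled ACBI-1 over DMSO libraries in 0.1515% of genes. For MOLT-4 the authors' deposited table equalled ACBI-1 over DMSO as labelled in 100% of 27777 genes. No label states which of the count table and the deposited table of DND-41 holds the treatments as they were given. DND-41 results are therefore given for the libraries as labelled and, separately, as the authors' deposited table states them.

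**Figure D1:**
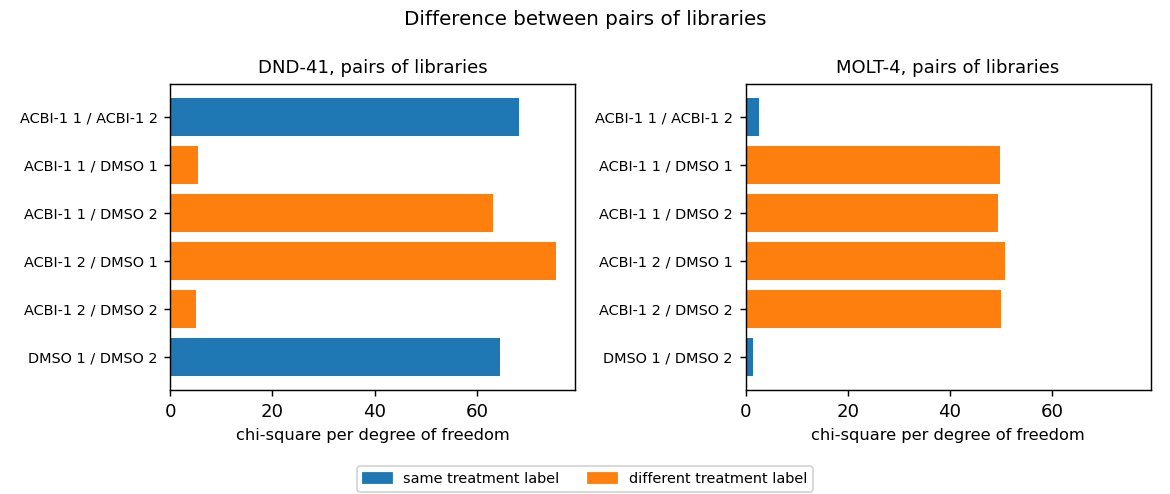
Each bar is a pair of libraries of DND-41 (left) or MOLT-4 (right) and its length is their difference, as chi-square per degree of freedom across genes (no unit, 1 is counting noise alone), blue for pairs with the same treatment label and orange for different labels. In MOLT-4 the short bars (1.52 and 2.65) are pairs with the same label, and in DND-41 the short bars (5.09 and 5.49) are pairs with the same replicate number and different labels.

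The first comparison asked which transcripts ACBI-1 changed in MOLT-4. HES1 (ENSG00000114315), a repressor that NOTCH1 switches on, fell with ACBI-1 from 53.9 ± 1.19 to 0.822 ± 0.0353 CPM (SD, n = 2), a log2 fold change of -6.02 (SE 0.121, adjusted p = 6.67e-36 by edgeR quasi-likelihood with Benjamini-Hochberg). NOTCH1 (ENSG00000148400), the receptor itself, fell from 800 ± 2.81 to 172 ± 8.76 CPM (log2 fold change -2.22, SE 0.0381, edgeR adjusted p = 3.21e-38). CCR9 (ENSG00000173585), a chemokine receptor that guides T cells to the gut, fell from 87.2 ± 0.348 to 2.56 ± 0.169 CPM (log2 fold change -5.09, SE 0.0879, edgeR adjusted p = 3.21e-38). PTMS (ENSG00000159335), which encodes parathymosin, rose from 0.973 ± 0.101 to 25.5 ± 1.85 CPM (log2 fold change 4.71, SE 0.147, edgeR adjusted p = 8.65e-29).

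Of 14618 genes tested in MOLT-4, edgeR called 8533 (58.4%), 4120 higher and 4413 lower with ACBI-1. At least 2-fold changes were found in 880 genes that rose and 705 that fell. Scaling by total counts in place of TMM moved the median log2 fold change of all genes by 0.119 and gave 5804 genes higher and 3031 lower, so directions of small changes are relative to the TMM scaling. Against a change of 1.5-fold 1737 genes passed, and 544 passed when the spread was shared with the DND-41 libraries.

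Among the genes that rose most in MOLT-4 by the rule for named genes, PTK2, the focal adhesion kinase, rose from 1.23 ± 0.403 to 23.6 ± 2.03 CPM (SD, n = 2; log2 fold change 4.25), and CTTN, the actin-binding protein cortactin, from 2.87 ± 0.234 to 34.3 ± 0.656 CPM (3.57). PLXDC1 rose from 1.4957 ± 0.370 to 32.7 ± 0.122 CPM (4.44). TRIB1, a pseudokinase that promotes protein degradation, rose from 1.28 ± 0.269 to 20.8 ± 0.0348 CPM (4.01), and NOG, the BMP antagonist noggin, from 0.688 ± 0.0334 to 8.78 ± 0.450 CPM (3.66). The other genes with the largest log2 fold changes were PRRT2 (4.43), HID1 (3.95), ARHGEF12 (3.62), which activates RHOA, DAB1 (3.57), FAM63A (3.34) and EPN2 (3.27). A gene on the opposite strand held 226% of the counts of PRRT2, and the counting strand is unknown. Such shares, here and below, are over the 8 libraries of both lines, so the share in MOLT-4 alone can differ.

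By the same rule the largest falls in MOLT-4 were of ALDH3B2 (log2 fold change -6.70), which rested on 4 counts in both ACBI-1 libraries against 415 in DMSO, and of TMC8 (-6.03). TMC8 fell from 90.3 ± 0.928 to 1.38 ± 0.245 CPM (SD, n = 2). Over the 8 libraries of both lines its opposite-strand neighbour TMC6 held 45.3% of its counts. Of the 11574 counts of TMC8 in these libraries, MOLT-4 held 3805 with DMSO and 62 with ACBI-1, so the share in MOLT-4 can be larger. CD48 (-4.97), LTB (-4.93), which encodes lymphotoxin beta, SEMA7A (-4.21) and GPA33 (-3.75) fell as well. CD6, a receptor that tunes T-cell activation, fell from 71.2 ± 1.70 to 4.53 ± 0.0213 CPM (-3.97). VPREB1, a part of the surrogate light chain of the precursor B-cell receptor, fell from 13.9 ± 0.440 to 0.622 ± 0.00293 CPM (-4.47). LSP1 (-4.01), an actin-binding protein of leukocytes, and DOCK5 (-3.69), which activates RAC, completed the 12. Each of the 24 genes had an edgeR adjusted p of 5.76e-15 or less.

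**Figure D2:**
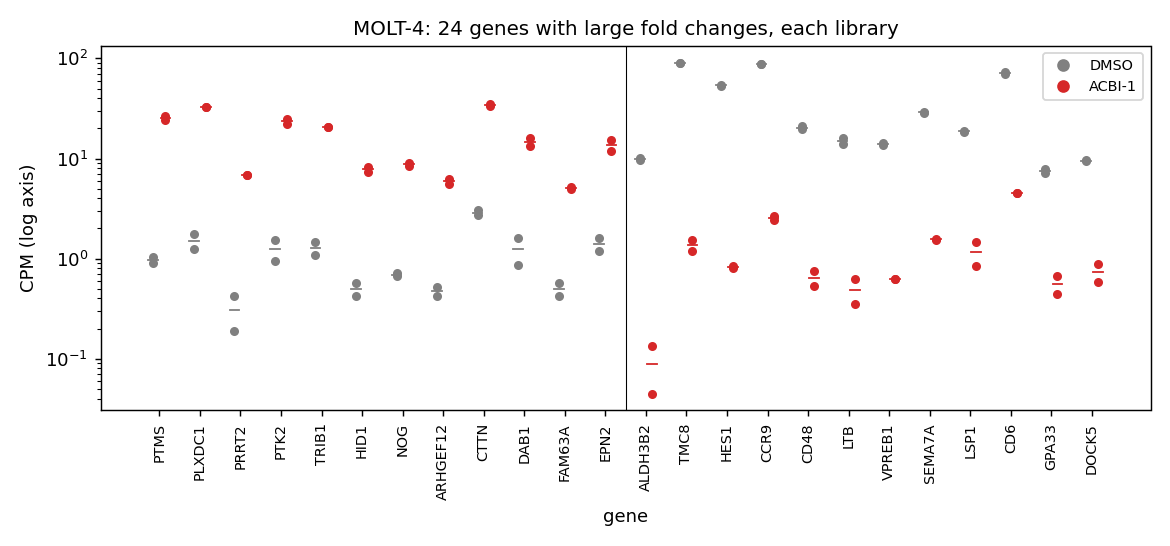
Depth-scaled counts (CPM, log axis) of 24 genes (horizontal axis) in MOLT-4 with DMSO (grey) or ACBI-1 (red), each point a library (n = 2 per group) and each short line the group mean. For each of the 24 genes both ACBI-1 libraries lie on the same side of both DMSO libraries, by the rule that chose them, and HES1 was 0.822 against 53.9 CPM.

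None of the transcripts of the proteins that ACBI-1 degrades passed the test as lower in MOLT-4. SMARCA2 was 25.7 ± 0.602 CPM with ACBI-1 and 26.9 ± 1.38 with DMSO (SD, n = 2; log2 fold change -0.06, SE 0.0696, edgeR adjusted p = 0.439). SMARCA4 rose from 591 ± 15.3 to 707 ± 25.1 CPM (log2 fold change 0.26, SE 0.0355, edgeR adjusted p = 3.09e-08). PBRM1 rose by a log2 fold change of 0.11 (SE 0.0364, edgeR adjusted p = 0.00736), and kept about this fold but lost the call without DMSO replicate 1 (0.12, adjusted p = 0.0701 by edgeR), DMSO replicate 2 (0.10, 0.159) or the low-count filter (0.09, 0.0591). VHL rose by a log2 fold change of 0.16 (SE 0.0447, edgeR adjusted p = 0.00221), and kept about this fold but lost the call without DMSO replicate 1 (0.15, edgeR adjusted p = 0.0629). PBRM1 and VHL did not pass in the authors' deposited table (DESeq2 adjusted p = 0.0788 and 0.0757). With the spread shared with DND-41, SMARCA4, PBRM1 and VHL did not pass (edgeR adjusted p = 0.162, 0.429 and 0.362). Protein levels were not measured.

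The groups of genes fixed beforehand moved as follows in MOLT-4, with counts of members past the edgeR threshold over all genes and, where these differed, counts adjusted over the list alone. Of 16 measured genes of the NOTCH1 pathway and its targets, 3 rose, 10 fell and 3 did not pass (adjusted over the list alone 3 and 10). NOTCH3 fell from 55.6 ± 4.28 to 4.51 ± 0.618 CPM (SD, n = 2; log2 fold change -3.62) and DTX1, a NOTCH target that encodes a ubiquitin ligase, from 62.8 ± 6.50 to 6.62 ± 0.786 CPM (-3.25). TRIB1, a member of this list, rose (4.01), as did CCND3, which encodes cyclin D3 (0.49). NRARP, also of this list, was higher in the authors' deposited table for MOLT-4 (2.73, SE 0.940, DESeq2 adjusted p = 0.0125). The median log2 fold change of the list was -1.01, lower than other genes by camera (adjusted p = 7.44e-15; adjusted p = 0.105 with an estimated correlation). All 40 measured MYC targets in ribosome and nucleotide synthesis fell (adjusted over the list alone 0 higher and 40 lower), with log2 fold changes from -1.001 to -0.11 and a median of -0.52 (camera adjusted p = 4.25e-19; adjusted p = 0.105 with an estimated correlation). The estimated correlation was 0.0402 for the NOTCH1 list and -0.0193 for the MYC targets. ODC1, the first enzyme of polyamine synthesis, fell from 563 ± 3.09 to 281 ± 4.75 CPM (SD, n = 2). NOLC1 (-0.82), SRM (-0.80), which makes spermidine, and the chaperone HSPD1 (-0.70) had the next smallest adjusted p.

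**Figure D3:**
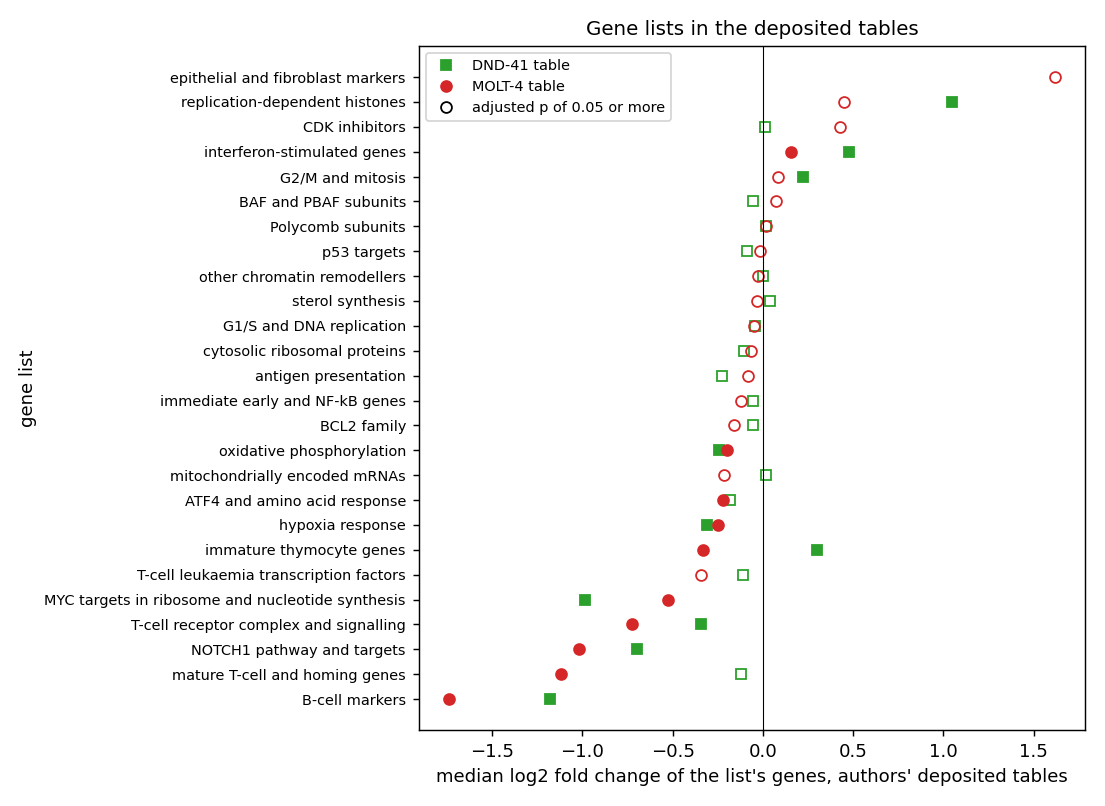
Median log2 fold change (horizontal axis) of each gene list (vertical axis) in the authors' deposited tables for DND-41 (green squares) and MOLT-4 (red circles), filled where the cameraPR adjusted p was below 0.05 and open otherwise. MYC targets were at -0.99 and -0.53, and immature thymocyte genes were at 0.30 in DND-41 and -0.33 in MOLT-4.

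In MOLT-4, 3 lists of T-cell genes passed as lower by camera at the preset correlation and 0 of them with an estimated one. Of 32 genes of the T-cell receptor complex and its signalling, 7 rose, 22 fell and 3 did not pass (median -0.71; camera adjusted p = 4.25e-19; adjusted p = 0.105 with an estimated correlation). CD7 fell from 139 ± 5.44 to 22.3 ± 3.03 CPM (SD, n = 2; log2 fold change -2.63), the adaptor LCP2 fell by 2.04 and UBASH3A, which dampens T-cell receptor signals, by 2.01 on the log2 scale. Among members of the receptor complex itself, CD3G rose (0.64) and CD3E did not pass (-0.04, edgeR adjusted p = 0.419). Of 18 immature thymocyte genes 4 rose, 10 fell and 4 did not pass (median -0.32; camera adjusted p = 1.9e-09; adjusted p = 0.105 with an estimated correlation), with the lipid-presenting proteins CD1B (-2.13), CD1A (-1.71) and CD1E (-1.5) among those that fell. Of 24 mature T-cell and homing genes 4 rose, 16 fell and 4 did not pass (median -1.10; camera adjusted p = 2.53e-13; adjusted p = 0.105 with an estimated correlation), among them the integrin ITGAL (-2.73), the hyaluronan receptor CD44 (-2.37) and the chemokine receptor CXCR4 (-1.79). Counts adjusted over the list alone were the same for these 3 lists. Among 22 T-cell leukaemia transcription factors 6 rose and 12 fell (median -0.33; camera adjusted p = 0.0795), with ERG higher (1.33) and GATA3 (-1.20), TAL1 (-1.03) and TOX (-0.92) lower, and a gene on the opposite strand held 14.2% of the counts of TOX.

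Interferon-stimulated genes were the 1 list past the threshold that was higher in MOLT-4. Of 34 measured, 18 rose, 3 fell and 13 did not pass, the same adjusted over the list alone (median 0.17; camera adjusted p = 0.00239; adjusted p = 0.212 with an estimated correlation and 0.133 with the spread shared with DND-41). SAMD9L rose from 42.6 ± 0.796 to 81.5 ± 1.31 CPM (SD, n = 2; log2 fold change 0.94), RSAD2 rose by 1.56 and IFI35 by 1.0 on the log2 scale. A gene on the opposite strand held 380% of the counts of RSAD2 over the 8 libraries of both lines. Among 14 antigen presentation genes 4 rose and 7 fell, with a median of -0.07 that was 0.05 under scaling by total counts (camera adjusted p = 0.151), and PSMB10 (-1.22), HLA-E (-0.77) and B2M (-0.39) fell. HLA genes resemble each other, and reads shared between them were not resolved. Among 26 immediate early and NF-kB genes 5 rose and 10 fell, with a median of -0.03 that was 0.09 under scaling by total counts (camera adjusted p = 0.4). DUSP2 (-1.46) and TNFAIP3 (-1.16) fell and BIRC3 (0.96) rose, and a gene on the opposite strand held 40.2% of the counts of TNFAIP3.

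Of 39 oxidative phosphorylation genes in MOLT-4, 1 rose, 26 fell and 12 did not pass (median -0.19; camera adjusted p = 0.0176; adjusted p = 0.507 with an estimated correlation), with CYCS, which encodes cytochrome c, at -0.66 and ATP5B at -0.39. Of 26 genes of ATF4 and the amino acid response 4 rose, 15 fell and 7 did not pass, or 5 and 15 adjusted over the list alone (median -0.21; camera adjusted p = 0.0367; adjusted p = 0.342 with an estimated correlation). SLC7A5 (-0.86) and SLC3A2 (-0.65), both chains of an amino acid transporter, fell. With scaling by total counts neither list passed (camera adjusted p = 0.0903 and 0.0725), and the ATF4 list did not pass with a filter of 1 CPM in 2 libraries (0.0672) or with the spread shared with DND-41 (0.0596). Among 28 hypoxia response genes 7 rose and 16 fell, or 8 and 16 adjusted over the list alone (median -0.24; camera adjusted p = 0.0709), and the glycolytic enzymes PGK1 (-0.71), ALDOA (-0.68), ENO1 (-0.67) and LDHA (-0.59) were among those that fell. The list passed without the low-count filter (0.0141), ACBI-1 replicate 1 (0.0345) or ACBI-1 replicate 2 (0.0194). Among 24 sterol synthesis genes 6 rose and 7 fell (camera adjusted p = 0.776), with a median of -0.02 that was 0.10 under scaling by total counts and a test direction upward. PMVK rose (0.72) and FDFT1 fell (-0.38). Of 13 mitochondrially encoded mRNAs 0 rose and 8 fell (median -0.21; camera adjusted p = 0.143), with MT-ND2 at -0.32. That list passed without ACBI-1 replicate 1 (0.00638), without the low-count filter (0.0165) and with the spread shared with DND-41 (0.038). Among 49 cytosolic ribosomal protein genes 5 rose and 19 fell, with a median of -0.05 that was 0.07 under scaling by total counts (camera adjusted p = 0.311, and 0.000411 without the low-count filter), and RPL8 fell by 0.47 on the log2 scale.

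Chromatin and growth control lists did not pass by camera in MOLT-4. By fry 10 lists that camera did not call passed. Fry asks whether the genes of a list changed at all, and 58.4% of the genes tested in MOLT-4 were called. Its passes therefore do not show a change particular to a list. The 10 lists were BAF and PBAF subunits (adjusted p = 0.0215 by fry), Polycomb subunits (0.0263), G2/M (0.0224), p53 targets (0.00776), CDK inhibitors (0.0115) and histones (0.0102). The rest were leukaemia factors (0.0201), antigen presentation (0.00965), NF-kB (0.00322) and hypoxia genes (0.00744). Other remodellers (0.543), G1/S (0.0955) and BCL2 family genes (0.0534) did not pass by fry. Among 27 BAF and PBAF subunits 13 rose and 7 fell (median 0.08; camera adjusted p = 0.122, and 0.028 with scaling by total counts). GLTSCR1L, a subunit of the non-canonical BAF complex, rose from 7.64 ± 0.136 to 30.5 ± 0.0807 CPM (SD, n = 2; log2 fold change 2.0), PHF10 rose (0.52) with an opposite-strand gene at 29.4% of its counts, and DPF3 (-2.03) and BCL7A (-0.59) fell. Among 19 other chromatin remodellers 8 rose and 6 fell (camera adjusted p = 0.654), with a median of -0.01 that was 0.10 under scaling by total counts and a test direction upward, CHD3 higher (1.0) and CHD4 lower (-0.55). Among 25 Polycomb subunits 9 rose and 5 fell (median 0.03; camera adjusted p = 0.214), with CBX7 (1.10) and EZH1 (0.50) higher. Of 39 genes of G1/S and DNA replication 9 rose and 14 fell, or 10 and 14 adjusted over the list alone, with a median of -0.04 that was 0.08 under scaling by total counts (camera adjusted p = 0.879), E2F2 higher (0.88) and UHRF1 lower (-0.87). Of 33 genes of G2/M and mitosis 15 rose and 6 fell, or 17 and 6 adjusted over the list alone (median 0.10; camera adjusted p = 0.0969), with the checkpoint kinases BUB1 (0.73) and TTK (0.46) higher. That list passed with scaling by total counts (0.0077) and without ACBI-1 replicate 1 (0.0475). Among 24 p53 targets 9 rose and 7 fell (camera adjusted p = 0.151), with a median of -0.00 that was 0.12 under scaling by total counts and a test direction upward, and with BTG2 (2.11), TP53INP1 (1.89) and DDB2 (0.80) higher and the death receptor FAS (-1.45) lower, where an opposite-strand gene held 15% of the counts of FAS. Of 5 CDK inhibitors 3 rose and 1 fell (median 0.44; camera adjusted p = 0.442), CDKN1B (0.49) and CDKN2C (0.44) among the former and CDKN2D (-0.71) the latter. Among 13 BCL2 family genes 3 rose and 7 fell, or 4 and 7 adjusted over the list alone (median -0.17; camera adjusted p = 0.497), with the cell death activator BMF higher (2.16) and BID (-0.62), PMAIP1 (-0.59) and MCL1 (-0.41) lower. Of 14 replication-dependent histone genes 5 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.49; camera adjusted p = 0.31), with HIST1H2AC at 1.10. The leukaemia transcription factor list, which also missed the threshold, passed without DMSO replicate 2 (0.03) and with the spread shared with DND-41 (0.0374).

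Few markers of other cell types passed the low-count filter in MOLT-4. Of 14 B-cell markers 6 were measured, of which 1 rose, 4 fell and 1 did not pass (median -1.72; camera adjusted p = 3.14e-08; adjusted p = 0.114 with an estimated correlation and 0.0817 with the spread shared with DND-41). IGLL1, which with VPREB1 forms the surrogate light chain, fell from 264 ± 6.28 to 38.5 ± 0.0555 CPM (SD, n = 2; log2 fold change -2.78), and CD79A (-3.51) and BLK (-0.47) fell. Other marker lists had too few members for a test. Of 2 myeloid markers measured AIF1 fell (-1.05), and the 1 measured NK marker, NKG7, fell (-1.80). Of 3 erythroid markers EPOR rose (0.63) and TFRC, the transferrin receptor, fell (-1.19), or 2 and 1 adjusted over the list alone. Of 3 epithelial and fibroblast markers VIM fell (-0.86). COL1A1 passed at 3.27, but its CPM with ACBI-1 was 7.16 ± 9.43 (SD, n = 2) and without ACBI-1 replicate 2 its log2 fold change was -0.58 (edgeR adjusted p = 0.519).

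The second comparison asked the same of DND-41. Between the libraries labelled ACBI-1 and DMSO no gene passed in tests that did not use the replicate number. These gave 0 of 14602 by edgeR (37 at an unadjusted p below 0.05), 0 by DESeq2 and 0 by limma-voom. The 37 genes are far fewer than the share of 0.05 that unchanged genes alone would give, so the edgeR p-values were too large here. With the replicate number as a block 1349 genes passed by edgeR (777 higher, 572 lower), although no label pairs the libraries. The gene values that follow are from the fit without the block. NOTCH1 was 591 CPM on average in the libraries labelled ACBI-1 and 524 in those labelled DMSO (n = 2, log2 fold change 0.17, SE 0.527, edgeR adjusted p = 1). HES1 was 56.9 ± 26.3 and 59.96 ± 28.7 CPM (SD, n = 2; log2 fold change -0.07). The log2 fold changes of SMARCA2 (0.12), SMARCA4 (0.05), PBRM1 (0.18) and VHL (0.07) did not pass either (edgeR adjusted p = 1 for each). With the replicate number as a block 1 of these genes gained the call. Without the block the common dispersion was 0.0795, against 0.00059 in MOLT-4. In simulated data with this spread and independent libraries the same test recovered 2.99% of 2-fold changes. The real libraries of the same number deviated together (correlation 0.849), so that share does not describe the test on them. The 0 calls of the fit without the block do not show that transcripts were unchanged.

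By camera 4 of 25 lists passed between the libraries as labelled in DND-41. Cytosolic ribosomal protein genes (median log2 fold change -0.19, adjusted p = 4.9e-21), oxidative phosphorylation genes (-0.13, adjusted p = 7.62e-06) and antigen presentation genes (-0.10, adjusted p = 0.0155) were lower, and other chromatin remodellers were higher (0.13, adjusted p = 7.63e-05). With an estimated correlation the camera results were adjusted p = 0.82, 0.937, 0.82 and 0.82 in that order, and 0 lists passed by fry. No member of these lists passed alone, and the most abundant ones were RPLP0 (-0.12), ATP5B (-0.06), B2M (-0.16) and SRCAP (0.23). The oxidative phosphorylation list did not pass without ACBI-1 replicate 2 (0.908) or DMSO replicate 1 (0.764, where its median was 0.03), nor did antigen presentation (0.861 and 0.809). Antigen presentation did not pass without the low-count filter (0.165) or with a filter of 1 CPM in 2 libraries (0.0745) either. The remodeller list did not pass without any 1 of the 4 libraries (0.0643 to 0.104) or the low-count filter (0.0817). In all 2 lists passed without that filter, and 10, 5, 5 and 7 without ACBI-1 replicate 1, ACBI-1 replicate 2, DMSO replicate 1 and DMSO replicate 2. The log2 fold changes between the libraries as labelled went up with exon length (Spearman rho 0.299 across 14149 genes). With that trend taken out of each library, the remodeller list (median 0.13 before and 0.03 after, camera adjusted p = 0.578) and antigen presentation (-0.10 and -0.06, adjusted p = 0.0924) did not pass. Ribosomal protein genes (-0.19 and -0.17, adjusted p = 8.29e-18) and oxidative phosphorylation genes (-0.13 and -0.10, adjusted p = 0.000111) still passed, and a remainder of the trend was left (rho 0.0499).

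The authors' deposited table for DND-41 states other results, with 5472 of 14883 genes called by DESeq2, 2255 higher and 3217 lower. Its fold changes are those of the libraries numbered 2 over those numbered 1, and its direction could not be checked against the labelled columns. If the column names are right, each number mixes both treatments and this table gives no ACBI-1 effect in either direction. PLXDC1 (log2 fold change 4.53, SE 0.284) and CTTN (4.06, SE 0.150) were highest in the authors' deposited table by the rule for named genes, followed by KLF2 (3.91, SE 0.319), a transcription factor of T-cell quiescence and homing. SYT11 (3.87), BMF (3.41) and BTG2 (3.35), an inhibitor of proliferation, were also higher in the authors' deposited table. Further genes there, higher in the authors' deposited table, were TBC1D2 (2.58), CCDC121 (2.49), SYP (2.48), GSTA4 (2.47) and YPEL3 (2.43). Lower in the authors' deposited table were IGJ (-3.92), the joining chain of immunoglobulins, the kinase MATK (-3.56), FAH (-3.51), TNFRSF8 (-3.45), which encodes CD30, and the cytotoxic granule gene NKG7 (-3.37). RGS16 (-3.36), TNFRSF1B (-3.31), C19orf77 (-3.23), EMR2 (-3.15), APOL4 (-3.07) and BATF3 (-2.85) were also lower in the authors' deposited table. SMARCA2 (-0.18), SMARCA4 (0.02), PBRM1 (0.05) and VHL (0.13) did not pass in the authors' deposited table (DESeq2 adjusted p = 0.144, 0.897, 0.724 and 0.256).

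By list, all 40 MYC targets were lower in the authors' deposited table for DND-41, from -1.72 to -0.37 (median -0.99; cameraPR adjusted p = 9.75e-44), and MYC itself was lower there (-1.64). Of 14 NOTCH1 pathway genes 3 were higher and 9 lower in the authors' deposited table (median -0.70; cameraPR adjusted p = 0.000236), with DTX1 (-1.61), NOTCH1 (-1.09) and HES1 (-1.03) lower and CR2 (2.09) higher. B-cell markers (0 higher and 4 lower of 6, median -1.18, cameraPR adjusted p = 1.36e-07) and hypoxia response genes (5 and 13 of 28, -0.31, adjusted p = 0.000911) were lower in the authors' deposited table. T-cell receptor genes (7 and 17 of 32, -0.34) and oxidative phosphorylation genes (0 and 19 of 39, -0.24) were lower in the authors' deposited table with a cameraPR adjusted p = 0.00439 for each. Higher in the authors' deposited table were interferon-stimulated genes (18 and 3 of 34, 0.48, cameraPR adjusted p = 2.19e-05), G2/M and mitosis genes (15 and 1 of 33, 0.23, adjusted p = 0.00027), immature thymocyte genes (10 and 5 of 17, 0.30, adjusted p = 0.00128) and replication-dependent histones (7 and 0 of 18, 1.05, adjusted p = 0.00498). BUB1 (1.32) and CD3G (1.33) were higher in the authors' deposited table. The other 15 lists tested with cameraPR did not pass, at adjusted p from 0.0533 for ATF4 and the amino acid response to 0.992 for other chromatin remodellers in the authors' deposited table.

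**Figure D4:**
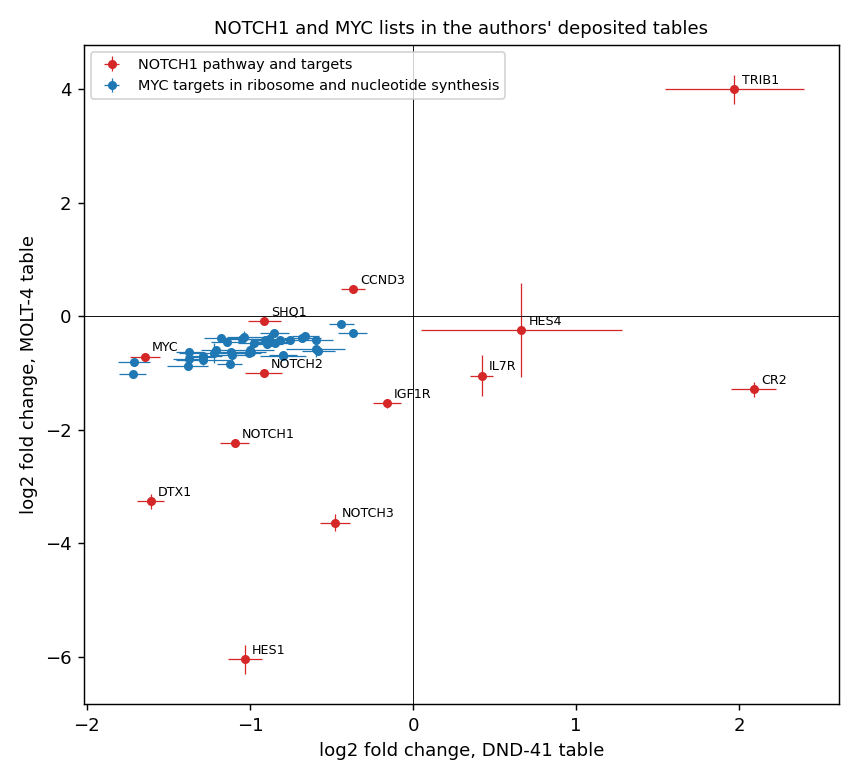
Log2 fold change in the authors' deposited tables for DND-41 (horizontal axis) and MOLT-4 (vertical axis), each point a gene of the NOTCH1 list (red) or of the MYC targets (blue) and each bar 1 standard error. All 40 MYC targets lie below 0 on both axes, while CR2 is at 2.09 in DND-41 and -1.28 in MOLT-4.

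The next comparison asked how far both lines responded alike. With the libraries as labelled and no block, 0 genes were called in the same direction in both lines, since DND-41 had no call. In DND-41 37 genes had an unadjusted p below 0.05 by edgeR, far fewer than unchanged genes alone would give, with 0 calls by DESeq2 and limma-voom. With the replicate number as a block, 697 genes were called in the same direction in both lines and 215 in opposite directions. Log2 fold changes correlated across 13272 genes with a Pearson r of 0.109 and a Spearman rho of 0.172, where genes are not independent replicates. The Pearson r was 0.504 without DND-41 ACBI-1 replicate 1, -0.438 without ACBI-1 replicate 2, -0.419 without DMSO replicate 1 and 0.481 without DMSO replicate 2. In both of the authors' deposited tables, 1194 genes were higher (344.9 expected if the calls were independent; odds ratio 12.8, 95% interval 11.5 to 14.2). Lower in both of the authors' deposited tables were 2094 genes (685.8 expected; odds ratio 20.4, interval 18.4 to 22.5). Fisher's exact test gave the odds ratios over 14053 genes, and 179 genes called in both of the authors' deposited tables had opposite directions. PLXDC1 (4.53 in DND-41 and 4.44 in MOLT-4), CTTN (4.06 and 3.56), SYT11 (3.87 and 3.20) and BMF (3.41 and 2.15), with SYP and GSTA4, led the shared higher genes of the authors' deposited tables. EMR2 (-3.15 and -3.68), FAH (-3.51 and -2.78), IFITM1 (-2.82 and -2.47) and CD7 (-2.43 and -2.65), with C19orf77 and RASSF2, led the shared lower genes of the authors' deposited tables. Across 11716 genes the log2 fold changes of the authors' deposited tables had a Pearson r of 0.635 and a Spearman rho of 0.682. All of these shared results rest on the authors' deposited table for DND-41 and on its direction. If the DND-41 column names are right, that table compares replicate numbers and gives no ACBI-1 effect. With its signs turned, 81 genes would be higher and 98 lower in both of the authors' deposited tables, 3288 opposite, and r would be -0.635.

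The last comparison asked which genes responded differently in the lines. In the fit of the libraries as labelled, without use of the replicate number, 63 of 16047 genes passed the edgeR interaction test. Of these, 20 had a higher and 43 a lower change in MOLT-4 than in DND-41. Each labelled DND-41 group mixes both replicate numbers. If the numbers hold the treatments, as in the authors' deposited table, the labelled DND-41 effect averages out. The differences would then mostly repeat the MOLT-4 changes, such as -6.02 for HES1 against a difference of -5.95. SEMA7A differed by a log2 fold change of -4.15 (SE 0.153, edgeR adjusted p = 0.00102) and PTMS by 4.85 (SE 0.304, edgeR adjusted p = 0.00959). In DND-41 as labelled, PTMS was 24.2 ± 4.90 CPM with ACBI-1 and 26.7 ± 4.90 with DMSO (SD, n = 2), and SEMA7A was 70.9 ± 1.90 and 73.6 ± 6.87. The differences of LTB (-4.84), HES1 (-5.95), TMEM71 (-5.08), CCR9 (-4.89) and IL16 (-4.35), an attractant of CD4 T cells, were negative. Those of PRRT2 (4.44), RGS12 (3.05), ABLIM1 (2.75), TTC7B (2.58) and PTPRF (2.34) were positive, with edgeR adjusted p up to 0.0418 for RGS12. CCR9 and PRRT2 averaged only 1.33 and 0.93 CPM over the DND-41 libraries, so a change there could hardly be seen. TMEM71 and IL16 were at 3.16 and 4.32 CPM with DMSO in MOLT-4 and rest on few counts. Over the 8 libraries of both lines STARD5, on the opposite strand, held 994 counts against 3675 of IL16 (27%). IL16 averaged 40.6 CPM in DND-41, so most of its counts came from there and the share in MOLT-4 can be larger. With the replicate number as a block 5860 genes passed (2767 higher, 3093 lower), although no label pairs the libraries. Without the block 389 genes passed by DESeq2, 154 with a higher and 235 with a lower change in MOLT-4, and against a 1.5-fold change 19 passed. The edgeR count fell to 0 without MOLT-4 ACBI-1 replicate 1 or 2, 1 without MOLT-4 DMSO replicate 1 or 2, and 19, 49, 28 and 6 without the DND-41 libraries ACBI-1 replicate 1, ACBI-1 replicate 2, DMSO replicate 1 and DMSO replicate 2.

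Between the authors' deposited tables, 1760 genes differed by the z test, 1047 with a more positive and 713 with a more negative log2 fold change in MOLT-4. If the DND-41 column names are right, these differences set the MOLT-4 response against a difference between replicate numbers. With all signs of the authors' deposited table for DND-41 turned, which the labelled columns do not exclude, 6740 differed (2907 and 3833), with HES1 at -7.08, SEMA7A at -4.14, PTMS at 5.07 and ANXA2 not past the threshold (-0.19). As deposited, HES1 differed by -5.02 (SE 0.281, z test adjusted p = 5.47e-68), SEMA7A by -4.32, LTB by -4.62 and TMC8 by -3.97 between the authors' deposited tables. PTMS (4.34), PTPRF (2.66) and ANXA2 (2.04) differed the other way between the authors' deposited tables. Among the MYC targets 30 of 40 differed in size between the authors' deposited tables with the same direction in both. Among immature thymocyte genes 12 differed, for example CD1A (0.82 in DND-41 and -1.73 in MOLT-4). Both results hold as deposited. With the signs of the DND-41 table turned, all 40 MYC targets would go opposite ways and CD1A would differ by -0.91. KLF2 was higher in the authors' deposited table for DND-41 (3.91) and did not pass in that for MOLT-4 (-1.12, DESeq2 adjusted p = 0.0623), a difference of -5.03 as deposited and 2.79 with the signs turned.

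Fold changes fitted here for MOLT-4 correlated with those of the authors' deposited table at a Pearson r of 0.9999 across genes, and 100% of the genes called here had the same sign in it. For DND-41 as labelled the Pearson r with the authors' deposited table was 0.113. It was 0.758 without ACBI-1 replicate 1, -0.730 without ACBI-1 replicate 2, -0.650 without DMSO replicate 1 and 0.762 without DMSO replicate 2.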

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

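For DND-41, the tests of exchanged names, of an unrelated batch and of a hidden ACBI-1 effect were chosen only after the results were seen, as were the test for B cells, the z test of the authors' tables and its repeat with the DND-41 table turned, and the bounds of the second length test were set after the first length value was known.

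A total of 63 genes stood out because their ACBI-1 effect differed between the lines in the libraries as labelled. Each labelled DND-41 group mixes both replicate numbers. If the numbers hold the treatments, as in the authors' deposited table, these differences would mostly repeat the MOLT-4 changes. The differences (MOLT-4 minus DND-41, log2) were 4.85 for PTMS, 4.44 for PRRT2, 3.05 for RGS12, 2.75 for ABLIM1, 2.58 for TTC7B and 2.34 for PTPRF. They were -5.95 for HES1, -5.08 for TMEM71, -4.89 for CCR9, -4.84 for LTB, -4.35 for IL16 and -4.15 for SEMA7A. By the z test 1760 genes, which include several of these, differed between the authors' deposited tables (6740 with the signs of the DND-41 table turned, as its direction could not be checked). If the DND-41 column names are right, that table compares replicate numbers and gives no ACBI-1 effect. The differences between the authors' deposited tables were 4.34 for PTMS, 2.66 for PTPRF, 2.04 for ANXA2, 2.03 for ATP6V0E2, 1.96 for BATF3 and 1.96 for AKAP6. On the negative side they were -5.02 for HES1, -4.62 for LTB, -4.32 for SEMA7A, -3.97 for TMC8, -3.56 for BHLHE23 and -3.37 for CR2 in the authors' deposited tables. With the signs turned, BATF3 (-3.74) and CR2 (0.81) reversed and ANXA2 (-0.19) and AKAP6 (-0.68) did not pass. The others kept their direction when turned, with PTMS at 5.07, PTPRF at 2.15, ATP6V0E2 at 1.37, HES1 at -7.08, LTB at -5.30, SEMA7A at -4.14, TMC8 at -8.12 and BHLHE23 at -1.53.

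The 4 DND-41 libraries fell into pairs by replicate number and not by the treatment in their names. For a culture or library batch unrelated to ACBI-1, the genes called between the numbers and in MOLT-4 were compared. If genes moved independently, such a batch would leave them going the same way about as often as not. Of 5150 such genes 92.6% went the same way. Genes can move together, with an estimated correlation of 0.997 for MYC targets in DND-41, so this share cannot exclude such a batch. A batch with effects like those of ACBI-1 was not tested. A candidate explanation is that 2 of the 4 columns carry each other's treatment name, for which the change of number 2 over number 1 followed the MOLT-4 response with a Pearson r of 0.607 across 13270 genes. No sample was reassigned on this ground, since the same values raised the explanation.

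Within each replicate number of DND-41, the columns named ACBI-1 and DMSO differed as well, with 1349 genes called when the number was a block. A gene length or RNA quality difference between libraries cannot be told apart from other causes, because the change correlated with exon length at a Spearman rho of 0.297, between the bounds set for and against it. A length trend as the whole cause cannot be told apart either. In a separate fit of the genes with a known length 1420 were called. Of these, 31.5% stayed called after the trend was removed, again between the bounds. If the columns carry the right names, an ACBI-1 effect hidden by the difference between the numbers may be present. Of 902 genes called within the numbers and in MOLT-4, 76.7% went the same way. With exchanged names, libraries of the same number would share a treatment, so the difference within numbers could not be an ACBI-1 effect.

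B-lineage genes such as IGLL1 were lower in MOLT-4 with ACBI-1. B cells in the DMSO cultures would bring CD74, HLA-DRA and MS4A1, abundant in B cells, but the highest of these reached 0.0912 CPM with DMSO, against 253 CPM for IGLL1, both without TMM scaling. No biological explanation was tested beyond the treatment groups.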

How the results depend on the processing

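The z test of the authors' tables, its repeat and the shared genes with the DND-41 table turned, their threshold of 0.01 and the length trend of the DND-41 lists were tests chosen only after the result was seen, and the other alternatives were planned. Under the alternatives, 1514 of the comparisons of named MOLT-4 genes kept their direction and side of the threshold and 161 lost the call, mostly in the fit of the 8 libraries or against a 1.5-fold change, where a wider spread or a stricter null is the construction. For SMARCA2, SMARCA4, PBRM1 and VHL in DND-41, 51 kept it and 1, with the replicate block, gained the call. For the interaction genes 114 kept it and 78 lost it. For MOLT-4 lists 259 kept it, 24 gained and 15 lost the call, and for the 4 called DND-41 lists 35 kept it and 20 lost it. With the replicate block, DND-41 gave 1349 genes (777 higher, 572 lower), 697 genes in the same direction in both lines, 5860 genes in the interaction and 7 lists in DND-41, because the block removes the difference between the numbers from the spread. Libraries with the same number deviated together across genes at a correlation of 0.849 in DND-41 and 0.00928 in MOLT-4. With the block the MOLT-4 lists of hypoxia response genes (camera adjusted p = 0.0411) and mitochondrially encoded mRNAs (0.0348) passed. MOLT-4 counts were 1737 against 1.5-fold and 544 in the fit of the 8 libraries. Interaction counts were 389 by DESeq2, 19 against 1.5-fold and 1760 by the z test, and the cause was not tested for DESeq2. Lists past the threshold with an estimated correlation were 0 in DND-41 and 0 in MOLT-4, and by fry, which does not compare a list with other genes, 0 and 19. With the exon length trend taken out 2 lists passed in DND-41, because part of the difference between the libraries follows exon length, and 4 passed on the same genes with the trend. Without the low-count filter 2 lists passed in DND-41 and the correlation between the lines was -0.00343, and the cause was not tested. Leaving out each library in turn gave 0 to 49 interaction genes, a correlation between the lines of -0.438 to 0.504, an r with the deposited DND-41 table of -0.730 to 0.762, and 5 to 10 lists in DND-41. COL1A1 in MOLT-4 ranged from -0.58 (without ACBI-1 replicate 2) to 4.22, and the median of oxidative phosphorylation genes in DND-41 from -0.262 to 0.0294 (without DMSO replicate 1), and the cause was not tested. At 0.01 the authors' deposited tables gave 4259 genes in DND-41, 2534 in the same direction in both and 1185 that differed. With all signs of the authors' deposited table for DND-41 turned, 6740 genes differed and 179 went in the same direction in both, because most genes called in both tables have the same sign as deposited. Depth was about equal, 21308737 to 22067644 counts, and limits genes of few counts.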

Other observations

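The tests of the gene families in this part were chosen only after the result was seen. The direction of the authors' deposited table for DND-41 could not be checked, and if the column names are right that table gives no ACBI-1 effect. With its signs turned, each of its directions in this part would reverse. All 7 measured genes of the GIMAP cluster, GTPases of lymphocyte survival, fell in MOLT-4 (median log2 fold change -2.16), and in the authors' deposited table for DND-41 3 of 7 were lower (median -0.45). TRBC2, the constant part of the T-cell receptor beta chain, fell from 3904 ± 35.5 to 458 ± 16.96 CPM in MOLT-4 (SD, n = 2; log2 fold change -3.09), and TRAC fell by 2.45 on the log2 scale. IFITM1 (-2.46) and IFITM2 (-1.88), interferon-induced membrane proteins, fell in MOLT-4 while IFITM3 (-0.21) did not pass, although 18 of 34 interferon-stimulated genes rose. In the authors' deposited table for DND-41 all 3 IFITM genes were lower (median -2.52).

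All 4 measured YPEL genes rose in MOLT-4 (median 1.08), and 4 of 5 were higher in the authors' deposited table for DND-41 (median 1.21). Of 17 glycolysis genes 14 fell and 1 rose in MOLT-4 (median -0.53), with GAPDH, often used as a reference gene, falling from 4060 ± 30.3 to 2440 ± 44.6 CPM (SD, n = 2; log2 fold change -0.73). In the authors' deposited table for DND-41 16 of the 17 were lower (median -0.83). With its signs turned these 16 would be higher, opposite to most of them in MOLT-4. The imprinted non-coding RNA H19 was lower in the authors' deposited table for DND-41 (-3.36).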
